A study of Mus musculus with 14 samples.

How the data were processed

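RNA from tibia was sequenced in 14 libraries of 5 groups, named here sham (n = 3), OVX-PBS (n = 3), OVX-HA (n = 3), OVX-PPA (n = 2) and OVX-ZA (n = 3), where OVX stands for ovariectomy. Per the labels' protocols, poly(A) RNA went into a stranded mRNA library kit and was read on an Illumina NextSeq as single reads of 75 nt. The submitters' processing notes list CASAVA 1.8.1, Bowtie2 2.2.5, STAR 2.7.8a, Partek and the mouse genome build mm10, with no role or order for any of them. The annotation, the counting tool and the statistical test of the authors are not given in the sources used here, and whether the counting used strand is not given either.

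The main input was the table of estimated counts that the authors deposited, with 1 value per gene symbol and library. Its values are not normalized, and 20.7% of them departed from a whole number by more than 0.01. The 8 largest values are rounded to 3 digits. A second table holds log2 values that the authors deposited as TMM-normalized counts according to its name. Each of its values equals log2 of the count plus 1e-04 minus 1 constant per library to within 0.0055, so it carries the same counts on a log2 scale. Both tables hold 55291 symbols, of which 17542 were at 0 in every library. All 14 columns of each table matched a sample title, and 0 columns were left unmapped. Symbols were looked up in the mm10 annotation, where 53292 of 55291 (96.4%) were found, and gene IDs and coordinates were taken from it.

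Estimated counts were rounded to whole numbers. Genes were kept with the edgeR filter by group, which left 21761 genes, and libraries were scaled by TMM. One edgeR quasi-likelihood fit (edgeR 4.0.16, R 4.3.3) held all 14 libraries with a mean per group and no covariate. It gave 10 two-sided comparisons, each adjusted by Benjamini-Hochberg with an FDR of 0.05. The fit had 9 residual degrees of freedom and a biological coefficient of variation of 25.0%. Group values in the text are means ± SD of TMM-scaled CPM (edgeR), and differences are log2 fold changes ± their standard error from the fit. Intervals of single genes are 95% intervals from the same fit.

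Before the data were examined, 28 gene lists, the tests and the rule for genes to name were fixed. The lists cover bone cells, marrow blood cells, marrow stroma and fat, muscle, tendon, cartilage, vessels and some pathways. Lists were tested on TMM log2 CPM (prior count 2) with limma camera (limma 3.58.1), which asks whether a list moved relative to the other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and limma fry, which asks whether the genes of a list move on balance one way, were the alternatives. For each list the difference of the mean log2 CPM of its members between groups is given with a 95% interval. The ribosomal protein list was defined by a name pattern, which also catches kinases of the Rps6ka family.

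The rule for named genes was as follows. In the comparisons of OVX-PBS with sham and of each compound with OVX-PBS, up to 8 genes per direction that passed the FDR, did not overlap between groups and reached 2 CPM were to be named. Where fewer than 4 passed in a direction, the 4 with the smallest unadjusted p were named and said not to pass. In each list called by camera the 4 members with the smallest p were named, and 14 bone, fat and receptor genes were always named. In the other 6 comparisons 3 genes per direction were named. Predicted genes, pseudogenes and receptor segments were left out of the first part of the rule. For lists in which no member passed the adjustment over the list alone, the text prints fewer than the 4 members to keep the account short. Genes named outside the rule are said to be so. Some genes that the rule or the marker lists select are not reported here.

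The scripts were tested on simulated counts drawn from the means, spreads and library sizes of the real libraries. In the simulated comparison of OVX-ZA with OVX-PBS (21440 genes), edgeR recovered 55 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, with 5 false calls, and DESeq2 recovered 71 and 94 with 49 false calls. In the simulated comparison of OVX-PPA with OVX-PBS (21453 genes), edgeR recovered 32 and 87 of 100 with 1 false call, and DESeq2 60 and 94 with 37 false calls. Camera found an osteoclast list shifted by 0.6 in both, with adjusted p of 1.08e-14 and 5.03e-08, and called 0 of the other 27 lists. These draws treated genes as independent and held neither outlying libraries nor a shared tissue mixture. The recovered shares are therefore not the power of the real comparisons, and genes that did not pass there may still have changed. A harder test redrew whole libraries with no group effect, which keeps the real correlation between genes. There the preset correlation called at least 1 list in 99 or 100 of 100 draws in each of 7 comparisons, with a median of 12 of 28 lists (13 for OVX-HA against OVX-ZA), while the estimated correlation called 0. The highest count was 22, for OVX-PPA against OVX-ZA. List calls at the preset correlation are therefore given with the result at the estimated correlation in the report. The shifted osteoclast list was not tested at the estimated correlation, so whether that setting can call a list that moved is unknown. A list not called there may still have moved.

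Library totals ran from 11.9 to 35.4 M estimated counts. The median standard error of a log2 fold change was 0.233 in the comparison of OVX-PBS with sham and 0.263 in that of OVX-PPA with OVX-PBS. The alternatives set beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, only the 2 groups compared, the replicate number as a block, the muscle list mean as a covariate, limma on the deposited log2 table (as log2 of the linear value plus 1), and leaving out each replicate in turn. A covariate for central nervous system transcripts, and a fit without the 2 libraries lowest in them, were added after seeing the data, as were 10 marker lists of other tissues. No library was left out of the fit and no sample was unassigned. The deposited log2 table was used only for 1 alternative, since the counts hold the same information.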

Results

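Tibia RNA was compared between sham-operated female mice (n = 3) and ovariectomized (OVX) mice given PBS (OVX-PBS, n = 3), hippuric acid (OVX-HA, n = 3), 3-(3-hydroxyphenyl)propionic acid (OVX-PPA, n = 2) or zoledronic acid (OVX-ZA, n = 3). Treatment lasted 8 weeks and began 2 to 4 days after surgery, and the doses are not given in the sources used here. Libraries held 29.2 to 32.6 M estimated counts in sham, 20.1 to 35.2 in OVX-PBS, 31.3 to 35.4 in OVX-HA, 18.7 to 29.7 in OVX-PPA and 11.9 to 25.1 in OVX-ZA. In all, 21761 genes were tested with edgeR quasi-likelihood and Benjamini-Hochberg (BH) adjustment. The labels do not say that each library came from a separate animal, so the p-values measure spread between samples. Muscle transcripts took up 6.76 ± 1.77% of counts in sham, 7.90 ± 1.13% in OVX-PBS, 7.20 ± 1.89% in OVX-HA, 6.77 ± 0.510% in OVX-PPA and 8.35 ± 1.19% in OVX-ZA.

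Transcripts of nervous tissue set 2 of the 14 libraries apart. Mobp, which encodes a myelin protein of oligodendrocytes, read 158 to 501 CPM in 12 libraries, 1.17 in OVX-HA replicate 2 and 5.13 in OVX-PBS replicate 1. Slc6a5, the glycine transporter of spinal cord and brainstem neurons, ran from 30.8 to 85.1 CPM in the same 12 libraries against 0.496 and 0.159. Scn10a (20 to 72.9 CPM) and Calca (28.4 to 80.4 CPM), which mark sensory neurons, were present in all 14 libraries. The lymph node gene Glycam1 read 32.9 CPM in sham replicate 3, 15.0 in OVX-ZA replicate 1 and 39.3 in OVX-ZA replicate 2, and at most 0.846 elsewhere. Alb, a liver transcript, read 13.3 and 13.1 CPM in sham replicates 1 and 2 and at most 3.55 elsewhere. The first principal component of 1000 variable genes held 52.4% of the variance and placed OVX-HA replicate 2 (71.6) and OVX-PBS replicate 1 (69.7) far from the other 12 libraries (-23.4 to 7.51). Tbx4, a transcription factor of the hindlimb, read a median of 1.02 CPM and the trunk gene Hoxa7 23.8, so how much of the RNA came from tibia is uncertain. A list of central nervous system genes, chosen after its values were seen, averaged 4.94 ± 0.63 log2 CPM in sham, 2.73 ± 3.41 in OVX-PBS, 3.00 ± 4.18 in OVX-HA, 5.09 ± 0.18 in OVX-PPA and 4.68 ± 0.71 in OVX-ZA.

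**Figure D1:**
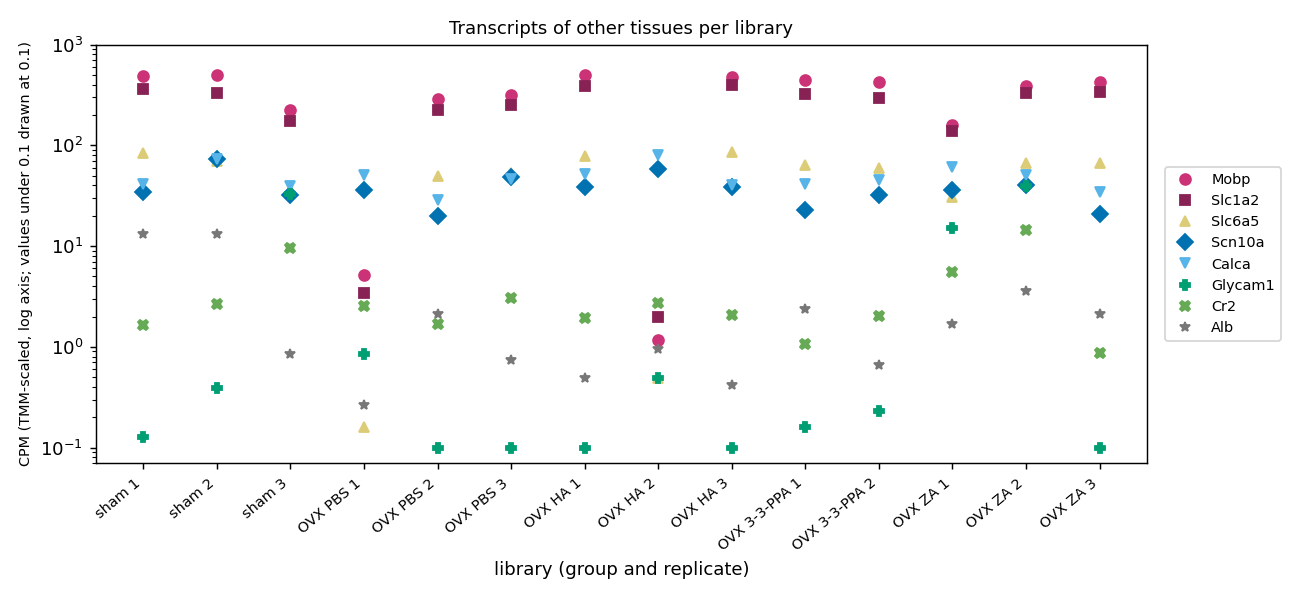
Transcripts of other tissues in each library, in CPM on a log axis with values below 0.1 drawn at 0.1. Mobp read 1.17 in OVX-HA replicate 2 and 5.13 in OVX-PBS replicate 1, against 158 to 501 in the other 12 libraries.

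What did ovariectomy alter in the tibia? Genes of tendon and periosteum and immediate early genes averaged higher in OVX-PBS than in sham, with every OVX-PBS library above every sham library in the mean of each list. Part of both differences rested on OVX-PBS replicate 1. Tendon means were 6.01, 5.55 and 5.56 log2 CPM in OVX-PBS replicates 1 to 3, against 5.20, 5.22 and 5.32 in sham. Immediate early means were 4.93, 4.50 and 4.39, against 4.03, 3.99 and 4.31. Kera, a keratan sulfate proteoglycan of tendon and cornea, averaged 11.1 ± 5.04 CPM in OVX-PBS and 4.95 ± 1.07 in sham (n = 3 each; log2 difference 1.16 ± 0.312). Tnmd, a tendon membrane protein, averaged 11.5 ± 1.98 against 6.77 ± 0.232 (0.77). Fos, a subunit of the AP-1 transcription factor, averaged 35.6 ± 14.5 against 18.4 ± 3.68 CPM (0.95 ± 0.266), and Nr4a1, an orphan nuclear receptor, 95.9 ± 18.0 against 56.1 ± 20.6 (0.77). Col14a1 (ENSMUSG00000022371, mm10 chromosome 15, 55307750-55520803, + strand), a collagen bound to fibrils in tendon and skin, averaged 43.9 ± 6.58 against 27.8 ± 3.67 CPM (0.66 ± 0.125). No gene passed edgeR quasi-likelihood with BH adjustment (smallest adjusted p = 0.913), 594 genes had unadjusted p below 0.05 where chance alone would give 1088, and DESeq2 called 1 gene, Col14a1 (DESeq2 Wald test, BH adjusted p = 0.0487). The count of 594 hung on single libraries, with 1546 without sham replicate 3, 1426 without OVX-PBS replicate 3, 385 without sham replicate 2 and 269 without OVX-PBS replicate 1.

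The other genes with the smallest p in this comparison that were higher in OVX-PBS were Fam221b (26.5 ± 5.75 against 16.6 ± 0.263 CPM, log2 difference 0.67), Apold1 (12.3 ± 3.59 against 6.57 ± 0.521, 0.90) and Vpreb1, part of the surrogate light chain of pre-B cells (5.67 ± 1.03 against 2.07 ± 0.673, 1.45 ± 0.389). Tmem254a (-1.14 ± 0.292), Zfp618 (-0.52 ± 0.138), the glucocorticoid-responsive Fkbp5 (26.4 ± 4.14 against 38.6 ± 8.15 CPM, -0.55 ± 0.157) and Akr1d1 (0.019 ± 0.0166 against 11.8 ± 20.2 CPM, -8.77 ± 2.44) were lower, and none of these passed. Akr1d1 encodes a liver enzyme, and sham replicate 1 alone held nearly all of it (35.2 CPM, against 0.056 and 0.25 in sham replicates 2 and 3). The osteoclast protease Ctsk averaged 181 ± 4.95 CPM in OVX-PBS and 181 ± 43.1 in sham (-0.0032 ± 0.286), and Acp5, the osteoclast acid phosphatase, 267 ± 11.4 and 274 ± 41.4 (-0.04). Tnfsf11, which encodes RANKL, differed by -0.12 and its decoy receptor Tnfrsf11b by 0.06. The osteoblast genes Bglap (osteocalcin), Col1a1 and Alpl differed by 0.41 ± 0.293, 0.46 ± 0.313 and 0.21, and the osteocyte gene Sost by -0.16. Bglap lies beside the near-identical Bglap2 and Bglap3, so how reads were shared between the 3 is uncertain. The adipocyte genes Adipoq (0.14), Pparg (0.13), Plin1 (-0.0041) and Lep (0.66 ± 0.351), the nicotinic acid receptor Hcar2 (0.18) and the estrogen receptor Esr1 (25.8 ± 2.66 against 19.3 ± 3.68 CPM, 0.42 ± 0.150) also did not pass.

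The list test at its preset correlation was lenient. When whole libraries were redrawn without any group effect, it called a median of 12 of 28 lists in this comparison and the estimated correlation called 0. Whether the estimated correlation could call a list that had moved was not tested. By camera at the preset correlation, 14 of 28 lists were higher and 3 lower in OVX-PBS than in sham, with 0 members called over all genes, and 6 of 100 redraws called as many as these 17. With an estimated correlation none was called (adjusted p = 0.289 to 0.745 with an estimated correlation). Adjusted over the list alone, 6 immediate early genes (list median log2 difference 0.48), 4 tendon and periosteum genes (list median 0.38) and 1 B cell gene, Vpreb1 (list median 0.79), were called. Beside Fos and Nr4a1 the immediate early genes with the smallest p were Fosb (0.81) and Dusp1 (0.69), and beside Kera and Tnmd the tendon genes were Lum (0.62) and Aspn (0.47). In the B cell list Igll1, the partner of Vpreb1, averaged 6.51 ± 1.70 against 2.71 ± 0.448 CPM (1.27). The medians of the other lists that were higher were osteoblast 0.34 (Bglap2 0.63), chondrocyte 0.62 (Col9a1 1.49, Col10a1 1.06), muscle 0.36, erythroid 0.28, endothelial cell 0.17, cell cycle 0.26, interferon response 0.23, heat shock 0.11, collagen and matrix processing 0.25 (Col3a1 0.63, Serpinh1 0.56), ribosomal protein 0.11 and mitochondrially encoded 0.16. Part of these rested on OVX-PBS replicate 1, without which the difference from other genes went from 0.67 to 0.32 for chondrocyte, 0.37 to 0.24 for osteoblast, 0.32 to 0.10 for erythroid, 0.31 to 0.12 for cell cycle and 0.18 to 0.074 for ribosomal genes, and turned to -0.026 for mitochondrially encoded genes. With the central nervous system score as a covariate, chosen after the data were seen, erythroid (-0.10), cell cycle (-0.077) and ribosomal genes (-0.018) turned direction as well. The lists that were lower were T and NK cell (-0.29, Cd8b1 -2.08), mevalonate and cholesterol synthesis (-0.21, Dhcr7 -0.56) and immunoglobulin variable segments (-0.44), the last made of segments that share reads. Without sham replicate 3, which carried the lymph node transcripts, the T and NK cell difference from other genes turned to 0.14. The mitochondrial list also holds genes with nuclear copies, and its call is uncertain for that reason. Over 10 comparisons, 11 of 280 unadjusted 95% intervals of a list mean excluded 0, where chance alone would give 14. In this comparison they excluded 0 for tendon and periosteum (0.46, 0.14 to 0.78) and immediate early genes (0.50, 0.16 to 0.83), and not for osteoclast (-0.03, -0.52 to 0.46) or adipocyte genes (0.11, -0.69 to 0.92). In the sex steroid receptor list, which was not called, the median was 0.0022 and the mean -0.20, with Greb1, an estrogen-induced gene named after its value was seen, at -1.34 and Esr1 at 0.42 both passing over the list alone.

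Did hippuric acid, the glycine conjugate of benzoic acid, alter the tibia of ovariectomized mice? Adipocyte genes averaged lower in OVX-HA than in OVX-PBS, with 15 of 17 members of the list below and a median log2 difference of -0.41. Lpl, the lipase that frees fatty acids from lipoproteins, averaged 838 ± 126 CPM in OVX-HA and 1218 ± 348 in OVX-PBS (n = 3 each; -0.54 ± 0.250). Pparg, the main transcription factor of fat cell formation, averaged 15.2 ± 6.41 against 21.4 ± 4.69 (-0.49 ± 0.293). Brown fat transcripts differed between the same libraries, with Ucp1 at 139, 24.1 and 12.3 CPM in OVX-HA replicates 1 to 3 against 149, 184 and 71.6 in OVX-PBS, and Cidea at 97.6, 24.2 and 10.8 against 66.5, 115 and 37.5. The adipocyte list averaged 6.34, 5.61 and 5.39 log2 CPM against 6.41, 6.39 and 5.70 in those libraries. Cebpb (ENSMUSG00000056501, mm10 chromosome 2, 167688915-167690418, + strand), which acts early in fat cell formation and in myeloid cells, averaged 34.4 ± 5.22 against 61.7 ± 19.6 CPM (-0.84 ± 0.205). No gene passed edgeR quasi-likelihood with BH adjustment (smallest adjusted p = 1.00), 319 genes had unadjusted p below 0.05, and DESeq2 called 0. That count was 2813 without OVX-HA replicate 2, 490 without OVX-HA replicate 1, 1037 without OVX-PBS replicate 3, 154 without OVX-PBS replicate 1, 206 without OVX-PBS replicate 2 and 1351 in the libraries with central nervous system transcripts alone, with 0 genes passing in each.

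The other genes with the smallest p were the muscle-enriched mitochondrial carrier Slc25a34 (10.6 ± 3.58 against 24.9 ± 10.1 CPM, -1.23 ± 0.346), Barx2 (-0.77) and Plbd1 (-0.51), lower in OVX-HA, and Zfp618 (4.95 ± 0.112 against 3.56 ± 0.291 CPM, 0.47 ± 0.138), Hoxd4 (0.65), Cit (0.37) and Stk32b (0.70), higher. The group means of bone genes averaged over OVX-HA libraries that lay on opposite sides of OVX-PBS. OVX-HA replicates 1 and 3 were below every OVX-PBS library in the osteoclast list (4.66 and 4.6 against 4.82 to 5.01 log2 CPM) and the osteoblast list (5.44 and 5.16 against 5.56 to 5.96), and OVX-HA replicate 2, which lacked central nervous system transcripts, was above every one (5.27 and 6.32). Ctsk averaged 166 ± 74.7 CPM (-0.13), Acp5 244 ± 106 (-0.13), Bglap 216 ± 126 (0.16) and Col1a1 3150 ± 1591 (0.05). Tnfsf11 differed by 0.07, Tnfrsf11b by 0.31, Alpl by -0.02 and Sost by 0.18. Adipoq (91.3 ± 24.0 CPM, -0.29), Plin1 (87.3 ± 37.5, -0.36), Lep (12.1 ± 4.49, 0.24), Hcar2 (-0.28) and Esr1 (21.6 ± 2.95, -0.26) did not pass either.

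By camera 1 list was higher and 9 were lower in OVX-HA than in OVX-PBS, with 0 members called over all genes and 0 adjusted over the list alone. None was called with an estimated correlation (adjusted p = 0.825 to 0.949 with an estimated correlation). At the preset correlation 3 of the 10, endothelial cell, immediate early and interferon response, were called in every fit set beforehand, and the adipocyte list was not. Redraws without any group effect called a median of 12 lists, and 74 of 100 called as many as these 10. The medians were adipocyte -0.41 (Adig -0.66, Mrap -0.63), muscle -0.20, T and NK cell -0.25, monocyte and macrophage -0.24, endothelial cell -0.20, interferon response -0.32, immediate early -0.30, collagen and matrix processing -0.11 and mitochondrially encoded -0.22, with mevalonate and cholesterol synthesis higher at 0.18. All 21 interferon genes were below OVX-PBS, among them Rtp4 (-0.46), and so were all 13 endothelial genes. By library the interferon mean was 2.95 and 2.89 log2 CPM in OVX-HA replicates 1 and 3, below every OVX-PBS library (3.36 to 3.57), and 3.63 in OVX-HA replicate 2, above every one. Among the immediate early genes Jun differed by -0.48, Fos by -0.59 and Nr4a1 by -0.52. No interval of a list mean excluded 0, including adipocyte (-0.39, -1.19 to 0.42), interferon (-0.32, -0.82 to 0.18), osteoclast (-0.09, -0.58 to 0.40) and osteoblast (-0.10, -0.70 to 0.50). The collagen list turned to 0.0013 relative to other genes without OVX-PBS replicate 1. Mitochondrially encoded and immediate early differences rested in part on that library as well. It averaged 8.98 log2 CPM in mitochondrially encoded genes, against 8.43 and 8.12 in OVX-PBS replicates 2 and 3 and 8.19, 8.19 and 8.31 in OVX-HA. In immediate early genes it averaged 4.93, against 4.50 and 4.39 in OVX-PBS and 4.44, 4.40 and 4.18 in OVX-HA.

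Did 3-(3-hydroxyphenyl)propionic acid, with a ring hydroxyl and a propionic acid side chain, alter the tibia of ovariectomized mice? Heat shock genes averaged lower in OVX-PPA (n = 2) than in OVX-PBS (n = 3). Hspb1, a small heat shock protein, averaged 41.6 ± 1.28 CPM against 66.4 ± 14 (log2 difference -0.67 ± 0.185), and Hspa1b, an inducible HSP70, 14.2 against 23.4 (-0.72). Jun, an AP-1 subunit, averaged 68.4 against 111 CPM (-0.70). Bc1, a noncoding RNA of neurons, averaged 320 ± 261 against 27.2 ± 14.4 CPM (3.54 ± 0.872), with 504 and 136 CPM in the 2 OVX-PPA libraries. No gene passed edgeR quasi-likelihood with BH adjustment (smallest adjusted p = 1.00), 408 genes had unadjusted p below 0.05, and DESeq2 called 0.

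The other genes with the smallest p were Ugt1a6b (2.31 ± 0.336 against 0.724 ± 0.167 CPM, 1.66 ± 0.447), Pigh (0.49) and Tnk2os (0.71), higher in OVX-PPA, and Mrps26 (19.1 ± 0.821 against 26.2 ± 2.43, -0.46), Osgin1 (-0.56) and Fam221b (-0.66), lower. Ctsk averaged 178 ± 11.6 CPM (-0.02), Acp5 267 ± 26.1 (2.2e-04), Bglap 177 ± 25.8 (-0.12), Sost 9.94 ± 4.52 (0.51), Adipoq 107 ± 16.4 (-0.06), Pparg 22.5 ± 3.73 (0.07) and Plin1 110 ± 35 (-0.04) in OVX-PPA. Col1a1 differed by -0.14, Alpl by -0.10, Tnfrsf11b by 0.017, Lep by -0.22, Tnfsf11 by 0.14, Hcar2 by 0.09 and Esr1 by -0.07. By camera 7 lists were lower and 0 higher, with 0 members called over all genes, and none was called with an estimated correlation (adjusted p = 0.995 with an estimated correlation for each). Redraws of this comparison without any group effect called a median of 12 lists, and 93 of 100 called at least 7. Their medians were muscle -0.29, endothelial cell -0.16, interferon response -0.27 (Irf7 -0.56), immediate early -0.35 (Ier2 -0.50), heat shock -0.20 (Hspa1a -0.54, Bag3 -0.34), collagen and matrix processing -0.15 and ribosomal protein -0.16. Adjusted over the list alone, 1 heat shock gene, Hspb1, was called. The heat shock list mean was lower in both OVX-PPA libraries than in every OVX-PBS library (-0.26, -0.50 to -0.015). By library it was 6.29 and 6.15 log2 CPM in OVX-PPA, against 6.69, 6.42 and 6.32 in OVX-PBS replicates 1 to 3. Part of the difference thus rested on OVX-PBS replicate 1, which had little Mobp. The osteoclast list, which was not called, had a median of -0.01 and a mean of -0.02 (-0.56 to 0.53) while camera placed it above the other genes, and the adipocyte mean was -0.10 (-1.0 to 0.81). The ribosomal list turned to 0.0075 relative to other genes with the central nervous system score as a covariate.

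What did zoledronic acid, a nitrogen-containing bisphosphonate that blocks farnesyl diphosphate synthase, alter in ovariectomized mice? Osteoclast genes averaged higher and osteoblast genes lower in OVX-ZA than in OVX-PBS. Ocstamp (ENSMUSG00000027670, mm10 chromosome 2, 165393760-165400405, - strand), needed for fusion of osteoclast precursors, averaged 14.5 ± 5.36 CPM in OVX-ZA and 2.73 ± 0.345 in OVX-PBS (n = 3 each; log2 difference 2.40 ± 0.311). Dcstamp (ENSMUSG00000022303, chromosome 15, 39745930-39760938, + strand), the other fusion protein, averaged 17.4 ± 7.46 against 3.85 ± 0.522 (2.17 ± 0.342), and Ctsk (ENSMUSG00000028111, chromosome 3, 95499256-95509362, + strand) 479 ± 140 against 181 ± 4.95 (1.40 ± 0.292). Bglap (ENSMUSG00000074483, chromosome 3, 88383501-88384464, - strand) averaged 56.7 ± 5.41 against 193 ± 9.62 CPM (-1.77 ± 0.303). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224-94953042, + strand) averaged 1046 ± 280 against 3044 ± 514 (-1.54 ± 0.319), and Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814-4541544, + strand), the second chain of type I collagen, 1102 ± 212 against 3054 ± 493 (-1.47 ± 0.281). No gene passed edgeR quasi-likelihood with BH adjustment (smallest adjusted p = 0.111, Ocstamp), 731 genes had unadjusted p below 0.05, and DESeq2 called 32 (23 higher, 9 lower), among them Ocstamp (DESeq2 Wald test, BH adjusted p = 4.85e-10), Bglap (1.23e-04), Ctsk (0.00240) and Col1a1 (0.00302).

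**Figure D2:**
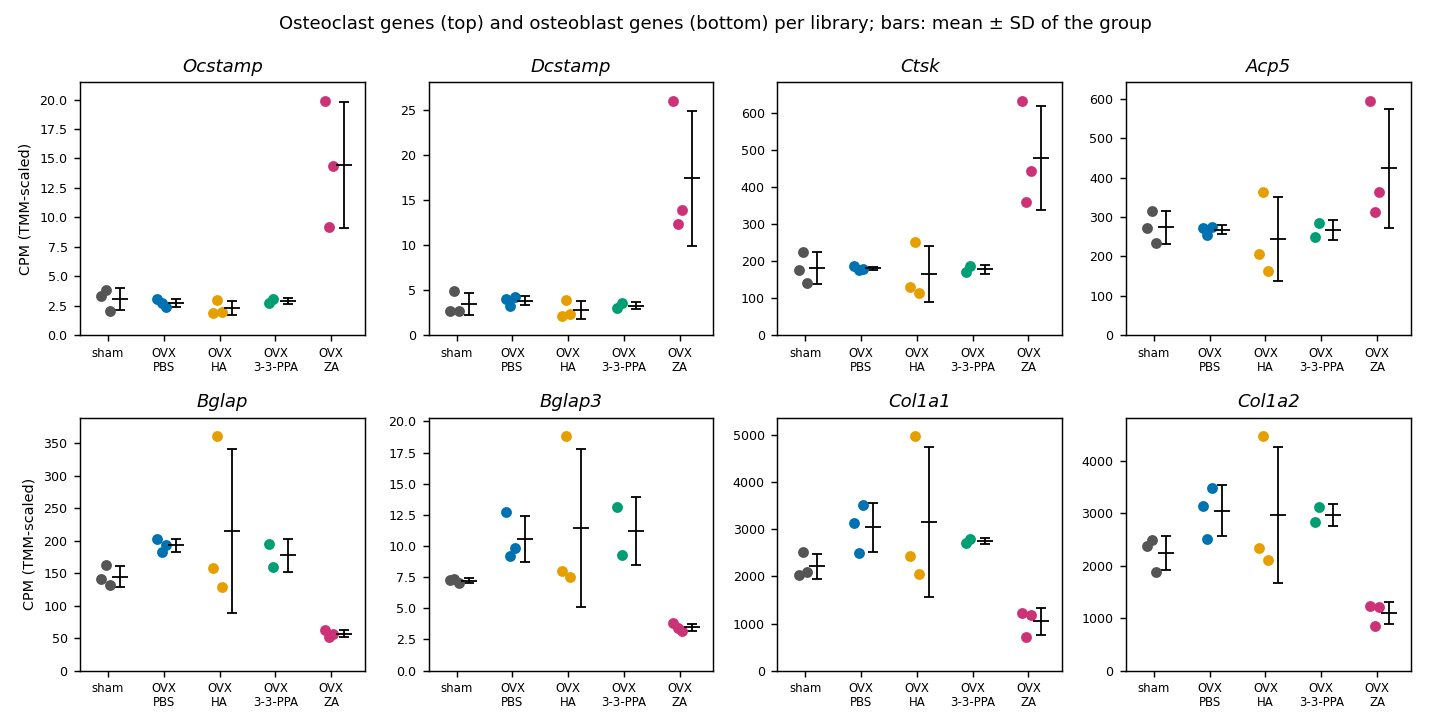
Osteoclast and osteoblast genes in each library by group, in CPM with mean ± SD. Ctsk averaged 479 ± 140 in OVX-ZA against 181 ± 4.95 in OVX-PBS, and Bglap 56.7 ± 5.41 against 193 ± 9.62.

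Cyp2s1 (12.8 ± 2.95 against 2.11 ± 0.864 CPM, 2.57 ± 0.378) and the chemokine Ccl9, made by osteoclasts (47.5 ± 11.5 against 17.6 ± 2.25, 1.43 ± 0.253), were the other 2 genes higher in OVX-ZA under the naming rule. Cfap161, a gene of cilia (0.30 ± 0.129 against 2.29 ± 0.619 CPM, -2.88 ± 0.444), and Bglap3 (3.47 ± 0.294 against 10.6 ± 1.85, -1.61 ± 0.316) were lower. Bglap, Bglap2 and Bglap3 are near-identical neighbors, so how the reads were shared between them is uncertain. Acp5 averaged 424 ± 150 against 267 ± 11.4 CPM (0.66 ± 0.286), Tnfsf11 3.54 ± 0.871 against 1.77 ± 0.30 (1.02 ± 0.364) and Sost 11.3 ± 4.14 against 6.95 (0.70). Tnfrsf11b (0.03), Alpl (55 ± 15.5 against 56.6 CPM, -0.04), Adipoq (-0.24), Pparg (-0.11), Plin1 (-0.15), Lep (-0.41), Hcar2 (-0.11) and Esr1 (0.14) differed little or with wide error.

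By camera the osteoclast list was higher in OVX-ZA (median 0.61, list mean 0.79, 0.31 to 1.28), with 11 of 17 members called adjusted over the list alone and 0 over all genes. Its adjusted p was 3.14e-18 at the preset correlation, and adjusted p = 0.406 with an estimated correlation. The osteoblast list was lower (median -0.60, list mean -0.68, -1.28 to -0.07), with 7 of 19 members called adjusted over the list alone, among them Bglap, Col1a2, Col1a1 and Cthrc1 (-1.22), and 0 over all genes. Its adjusted p was 3.17e-09, and adjusted p = 0.578 with an estimated correlation. Every OVX-ZA library was above every OVX-PBS library in the osteoclast mean, and Oscar, the osteoclast-associated receptor, averaged 13.5 ± 4.93 against 5.47 ± 0.327 CPM (1.30).

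Of the other lists in OVX-ZA against OVX-PBS, 4 were higher and 10 lower by camera, with 0 members called over all genes and none called with an estimated correlation (adjusted p = 0.406 to 0.601 with an estimated correlation over all 16 lists). Redraws without any group effect called a median of 12 lists, and 16 of 100 called at least 16. Higher were plasma cell (0.44, Prdm1 0.99), T and NK cell (0.51, Cd8b1 2.44, Cd3e 1.38), mevalonate and cholesterol synthesis (0.13) and immunoglobulin variable segments (0.44, Ighv1-71 3.26), where reads shared between segments make values uncertain. Lower were B cell (-0.72, Vpreb1 -1.27, Rag1 -1.43), erythroid (-0.56, Klf1 -0.79), cell cycle (-0.55, Top2a -0.63, Kif20a -0.68), tendon and periosteum (-0.20, Scx -0.55), endothelial cell (-0.16), interferon response (-0.26, Irf7 -0.64), immediate early (-0.23, Jun -0.60), heat shock (-0.25, Hspb1 -0.57, Hspa1b -0.73), collagen and matrix processing (-0.26, Col5a2 -0.72, Serpinh1 -0.70, Sparc -0.58) and ribosomal protein (-0.21). Adjusted over the list alone, 3 collagen genes, 2 heat shock genes and 1 gene each of the tendon, plasma cell and immunoglobulin lists were called. Part of the lower lists rested on OVX-PBS replicate 1, with means of 6.01 for tendon, 4.93 for immediate early and 6.59 log2 CPM for collagen genes. OVX-PBS replicates 2 and 3 read 5.55 and 5.56, 4.50 and 4.39, and 6.30 and 6.32. At the preset correlation 8 of the 16 lists were called in every fit set beforehand, and these 3 were not among them. The lymph node genes Glycam1 (15.0, 39.3 and 0 CPM in OVX-ZA replicates 1 to 3) and Cr2 (5.52, 14.4 and 0.874) were higher in replicates 1 and 2 than in replicate 3. The T and NK cell (1.62, 2.24 and 0.50 log2 CPM in OVX-ZA replicates 1 to 3), plasma cell (4.56, 4.59 and 3.75) and immunoglobulin lists (-0.18, 0.094 and -1.38) followed the same libraries. In lists that were not called, the mean and median differed in sign for muscle (-0.04 and 0.0025) and monocyte and macrophage genes (0.18 and -0.07). The heat shock mean was -0.30 (-0.51 to -0.08).

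**Figure D3:**
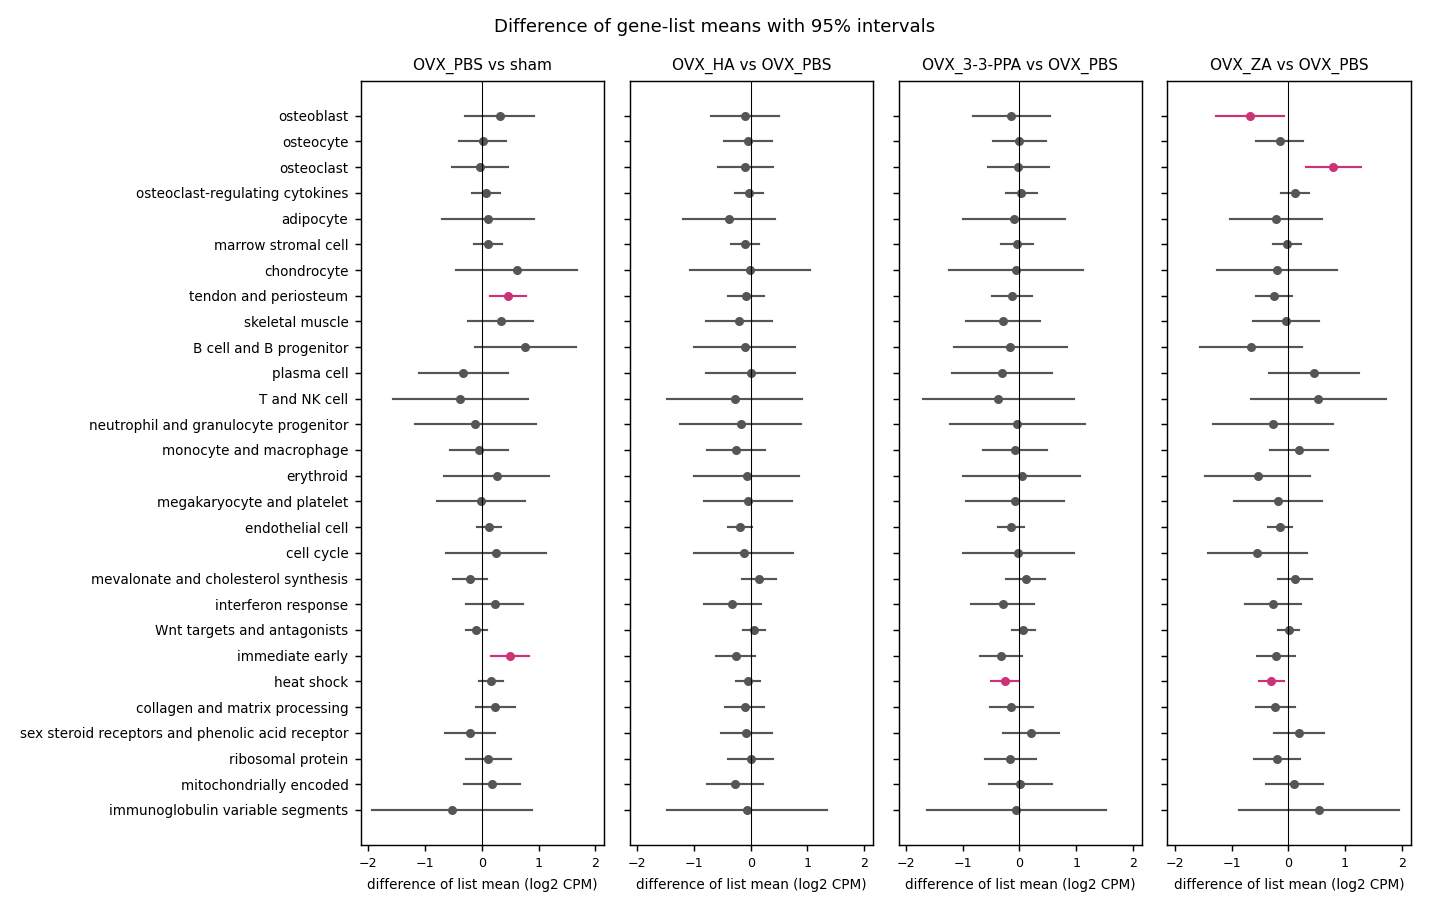
Difference of the list mean log2 CPM with its 95% interval for 28 lists in 4 comparisons. In OVX-ZA against OVX-PBS the osteoclast mean was 0.79 (0.31 to 1.28) and the osteoblast mean -0.68 (-1.28 to -0.07).

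Did OVX-HA and OVX-PPA differ from each other? Nr4a3, an orphan nuclear receptor, averaged 5.53 ± 1.47 CPM in OVX-HA (n = 3) and 2.55 ± 0.843 in OVX-PPA (n = 2), a log2 difference of 1.10 (0.29 to 1.91). Dio2, the enzyme that activates thyroid hormone, averaged 11.7 ± 1.06 against 19.6 ± 2.96 (-0.74), and the neuronal RNA Bc1 50.9 ± 47.8 against 320 ± 261 (-2.65, -4.50 to -0.81). Tle1 (0.35), Pagr1a (0.38) and Ccdc152 (-0.91) completed the genes with the smallest p. Pparg differed by -0.56 (-1.27 to 0.14), Adipoq by -0.23 (-0.92 to 0.45), Plin1 by -0.33 (-1.25 to 0.60), Ctsk by -0.11 (-0.80 to 0.59), Acp5 by -0.13 (-0.82 to 0.56), Bglap by 0.28 (-0.44 to 1.00), Col1a1 by 0.19 (-0.57 to 0.96), Sost by -0.33 (-1.45 to 0.79), Hcar2 by -0.37 (-1.24 to 0.51) and Esr1 by -0.19 (-0.55 to 0.17). The intervals of all 14 genes named in every comparison included 0, and their half-widths ran from 0.36 (Esr1) to 1.12 (Sost). By edgeR quasi-likelihood with BH adjustment 0 genes passed (smallest adjusted p = 1), 260 genes had unadjusted p below 0.05, and DESeq2 called 0. By camera 5 lists differed, namely adipocyte (-0.31), monocyte and macrophage (-0.14), heat shock (0.14), ribosomal protein (0.15) and mitochondrially encoded genes (-0.12), with 0 members called over all genes and adjusted p = 0.972 with an estimated correlation for each. Redraws without any group effect called a median of 12, and 99 of 100 called at least 5. Intervals of the list means included 0 for all lists, such as adipocyte (-0.29, -1.19 to 0.61) and osteoclast (-0.08, -0.62 to 0.47). Without OVX-PPA replicate 2 the monocyte list turned to 0.24 relative to other genes, and without OVX-HA replicate 2 the ribosomal list turned to -0.091.

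Did OVX-HA differ from OVX-ZA? Ocstamp was lower in OVX-HA than in OVX-ZA (2.27 ± 0.596 against 14.5 ± 5.36 CPM, n = 3 each; log2 difference -2.66 ± 0.313, -3.34 to -1.98). It was the 1 gene that passed edgeR quasi-likelihood with BH adjustment (adjusted p = 0.0411), beside 820 genes with unadjusted p below 0.05 and 29 called by DESeq2 (8 higher, 21 lower). Dcstamp averaged 2.78 ± 0.973 in OVX-HA against 17.4 ± 7.46 (-2.64 ± 0.347, adjusted p = 0.0661 by edgeR quasi-likelihood with BH), Ccl9 15.3 against 47.5 (-1.63), and Bglap 216 ± 126 against 56.7 ± 5.41 (1.93). Cfap161 (3.00) and Cthrc1, a secreted protein of matrix-forming cells (1.36), were the other named genes higher in OVX-HA. The Ocstamp call was lost when only the 2 groups were fitted, with replicate number as a block, with muscle as a covariate, and without OVX-HA replicate 1 or 3 or OVX-ZA replicate 1 or 3. Without OVX-HA replicate 2, 4 genes passed. The osteoclast list mean was lower in OVX-HA (-0.89, -1.38 to -0.40), with 11 members adjusted over the list alone and 1, Ocstamp, over all genes, and heat shock was higher (0.25, 0.04 to 0.47). Camera called 16 lists, 8 higher and 8 lower, and none with an estimated correlation (adjusted p = 0.230 to 0.668 with an estimated correlation). Redraws without any group effect called a median of 13, and 17 of 100 called at least 16. Medians were osteoblast 0.52 (6 members adjusted over the list alone), tendon 0.21, B cell 0.64 (3), erythroid 0.49, cell cycle 0.42, heat shock 0.25, collagen 0.16 (2), ribosomal 0.17, osteoclast -0.82, muscle -0.21, plasma cell -0.41 (1), T and NK cell -0.91, monocyte -0.19 (1), sex steroid receptors -0.24, mitochondrial -0.23 and immunoglobulin -0.65, with 0 members over all genes outside the osteoclast list. The T and NK cell, plasma cell and immunoglobulin lists were highest in OVX-ZA replicates 1 and 2, which carried Glycam1 (15.0 and 39.3 CPM, against 0 in replicate 3). Without OVX-HA replicate 2 the difference from other genes went from 0.56 to 0.18 for osteoblast and 0.54 to 0.27 for B cell genes, and from -0.90 to -1.16 for osteoclast genes. Erythroid (-0.13), cell cycle (-0.14), collagen (-0.076) and ribosomal (-0.091) lists turned direction relative to other genes without OVX-HA replicate 2. Of the 14 genes named in every comparison, 8 had intervals that included 0.

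How did OVX-PPA (n = 2) differ from OVX-ZA (n = 3)? Ocstamp averaged 2.91 ± 0.282 CPM in OVX-PPA (-2.30 ± 0.361), Dcstamp 3.26 (-2.40), Ccl9 16.0 ± 4.48 (-1.56) and Ctsk differed by -1.42 (-2.16 to -0.69). Col1a2 averaged 2977 ± 210 (1.43), Bglap 177 (1.65, 0.94 to 2.36), Bglap3 11.2 (1.69) and Col1a1 differed by 1.40 (0.65 to 2.15). By edgeR quasi-likelihood with BH adjustment 0 genes passed (smallest adjusted p = 0.717), 449 genes had unadjusted p below 0.05, and DESeq2 called 14 (5 higher, 9 lower). The osteoclast mean was lower in OVX-PPA (-0.81, -1.36 to -0.27), with 10 members adjusted over the list alone and 0 over all genes, and adjusted p = 0.270 with an estimated correlation. Camera called 10 lists, and none with an estimated correlation (adjusted p = 0.270 to 0.915 with an estimated correlation). Redraws without any group effect called a median of 12, and 82 of 100 called at least 10. Medians were osteoblast 0.46 (5 members adjusted over the list alone, 0 over all genes), B cell 0.54, erythroid 0.61, cell cycle 0.50, osteoclast -0.71, muscle -0.28, plasma cell -0.84, T and NK cell -0.77, monocyte -0.078 and immunoglobulin -0.55. As for OVX-HA, the lymphoid lists were set against OVX-ZA replicates 1 and 2 with lymph node transcripts. The B cell list turned to -0.056 without OVX-PPA replicate 2, and the monocyte and immunoglobulin lists to 0.10 and 0.40 without OVX-PPA replicate 1. Plasma cell and T and NK cell differences rested in part on OVX-PPA replicate 1. Plasma cell means were 2.99 and 4.08 log2 CPM in OVX-PPA replicates 1 and 2, against 4.56, 4.59 and 3.75 in OVX-ZA. T and NK cell means were 0.056 and 1.05, against 1.62, 2.24 and 0.50.

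How far did treated mice stand from sham mice? Col14a1 averaged 41.0 ± 1.22 CPM in OVX-HA (n = 3) and 38.0 ± 0.777 in OVX-PPA (n = 2) against 27.8 ± 3.67 in sham (0.56 and 0.45). Il4ra, the interleukin 4 receptor, averaged 18.8 ± 2.38 in OVX-HA and 20.2 in OVX-PPA against 33.3 ± 3.85 (-0.83 and -0.72). Vpreb1 (1.44), Rpl32l (0.84), Fkbp5 (-0.65) and Angptl8, a hormone of fat and liver (-1.67), were the other named genes in OVX-HA, and Igll1 (1.42), Bcl7a (0.46), Osgin1 (-0.65) and Tppp3 (-0.42) in OVX-PPA. In OVX-ZA, Ocstamp (2.23), Dcstamp (2.32) and Ccl9 (1.46) were higher than in sham, and Bglap (-1.36), Cfap161 (-2.72) and Sln, a calcium pump regulator of muscle (-0.78), were lower. In none of the 3 did a gene pass edgeR quasi-likelihood with BH adjustment (smallest adjusted p = 1, 1 and 0.207), 378, 397 and 607 genes had unadjusted p below 0.05 in OVX-HA, OVX-PPA and OVX-ZA, and DESeq2 called 0, 0 and 15. The interval of the list mean excluded 0 for tendon and periosteum genes in OVX-HA (0.39, 0.07 to 0.70) and for osteoclast genes in OVX-ZA (0.76, 0.27 to 1.25).

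Did treatment return genes toward sham? By edgeR quasi-likelihood 0 genes were called for ovariectomy and 0 for each treatment against OVX-PBS, so calls could not show a return toward sham or a response shared by treatments. Across all genes the ovariectomy difference correlated with the treatment difference at -0.58 for OVX-HA, -0.66 for OVX-PPA and -0.68 for OVX-ZA. The shared OVX-PBS libraries alone give negative values, with -0.51, -0.45 and -0.49 in simulations without any effect and a mean of -0.46 (-0.88 to 0.20), -0.41 (-0.84 to 0.32) and -0.46 (-0.87 to 0.22) when whole libraries were redrawn, and each observed value lay inside its redrawn interval. The 3 treatments correlated with each other at 0.57 (OVX-HA and OVX-PPA), 0.49 (OVX-HA and OVX-ZA) and 0.59 (OVX-PPA and OVX-ZA), against 0.45, 0.49 and 0.43 in the simulations. Redrawn whole libraries gave 0.42 (-0.30 to 0.86), 0.47 (-0.26 to 0.89) and 0.41 (-0.28 to 0.85), and these intervals held every observed value. With 3 OVX-PBS libraries the controls could not be split.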

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

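Chosen only after the result was seen were the index hopping test, the marrow test, the regrouping of libraries, and the use of the muscle covariate and of leaving out sham replicate 3 or OVX-PBS replicate 1 as tests of an explanation, although these 3 fits were set beforehand. Ocstamp differed between OVX-HA and OVX-ZA by a log2 difference of -2.66 and was picked out as a gene that differed directly between treatments. Lists that differed directly between treatments were picked out as well, 5 for OVX-HA against OVX-PPA, 16 for OVX-HA against OVX-ZA and 10 for OVX-PPA against OVX-ZA, all at the preset correlation, and 0 were called in each with an estimated correlation. Redraws of these comparisons without any group effect called at least as many lists in 99, 17 and 82 of 100 draws. The direct tests of difference gave these values, so they do not rest on a gene passing in 1 treatment and failing in another.

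Osteoclast genes above and osteoblast genes below OVX-PBS in OVX-ZA were weighed against 3 other explanations. Whether a difference in library size played a part was not decided. Thinning every library to the smallest total left an osteoclast median of 0.67 and an osteoblast median of -0.62 (edgeR log2 fold changes). Thinning keeps the expected share of each gene in a library, so these values could hardly have moved whatever the cause. Muscle list means were close in OVX-ZA and OVX-PBS (difference -0.04, -0.62 to 0.54), which gives no sign that muscle set the groups apart. The osteoclast difference from other genes was 0.78 under the muscle covariate. With means this close the covariate could hardly have moved it, so that value does not decide. A lower share of blood-forming marrow cells would raise the genes of every other cell type alike, and the osteoblast median was -0.60 (list mean -0.68, -1.28 to -0.07), so it did not account for the pattern as a whole. Some blood cell lists were lower in OVX-ZA too (medians erythroid -0.56, B cell -0.72, neutrophil -0.30), with intervals of the mean of -1.47 to 0.39, -1.55 to 0.23 and -1.34 to 0.79. Others were higher, with means of 0.53 for T and NK cell, 0.46 for plasma cell and 0.18 for monocyte and macrophage genes, whose intervals also included 0. A lower marrow share as part of the higher osteoclast genes or of the lower osteoblast genes was not excluded.

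Central nervous system transcripts in 12 of 14 libraries were weighed against 3 explanations. Central nervous system tissue in the sampled material predicted that a second list would be low in the same 2 libraries, and 90.9% of its tested genes were, with Enpp6 the exception. The other explanations predict this as well, so the value does not tell them apart. Reads carried over from another library by index hopping predicted more such reads in smaller libraries, while the Spearman correlation with library total was 0.34 (permutation p = 0.274). That value rested in part on the small libraries OVX-ZA replicate 1 and OVX-PPA replicate 1, without which it was 0.19. Whether vertebral column was sampled in place of the tibia could not be told, with Tbx4, a hindlimb transcription factor, at a median of 1.02 CPM and the trunk genes Hoxa7 and Hoxc6 at 23.8 and 20.5. In OVX-HA replicate 2 and OVX-PBS replicate 1, Hoxa7 (19.3 and 19.1 CPM) and Hoxc6 (18.6 and 22.9) kept most of their level without the central nervous system transcripts. Tbx4 (1.14 and 1.37) was not lower there either.

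T and NK cell genes below and B cell genes above sham in OVX-PBS were weighed against 2 explanations. Sham replicate 3 carried lymph node transcripts (Glycam1 at 32.9 CPM) and the highest T and NK cell mean of sham (2.17 against 0.70 and 1.04 log2 CPM). The difference from other genes was 0.14 without it, but leaving out the highest library moves the value that way in any case. Over all groups, the libraries with Glycam1 had the highest T and NK cell means. These were 2.24 and 1.62 in OVX-ZA replicates 2 and 1 (Glycam1 39.3 and 15.0 CPM) and 2.17 in sham replicate 3, against at most 1.17 elsewhere. The match goes with lymph node tissue but rests on few libraries, so the cause stays open. OVX-PBS replicate 1 did not carry the B cell part, since its B cell list mean was the lowest of its group (4.05 against 4.21 and 4.89 log2 CPM). The value of 0.97 without that library adds nothing, as leaving out the lowest library raises the group mean.

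The 6 libraries of a comparison with 3 a side can be parted in 10 ways, too few for a share under 0.05. Where the real count was 0, every parting was as large by definition. For genes, the count was as large as the real one in 10 of 10 partings for OVX-PBS against sham (real 0, highest other 0), OVX-HA against OVX-PBS (0, 1), OVX-ZA against OVX-PBS (0, 0), OVX-HA against sham (0, 2) and OVX-ZA against sham (0, 0), and in 1 for OVX-HA against OVX-ZA (1, 0). For lists it was as large in 1 for OVX-PBS against sham (17, 15), 8 for OVX-HA against OVX-PBS (10, 15), 2 for OVX-ZA against OVX-PBS (16, 20) and 2 for OVX-HA against OVX-ZA (16, 20).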

How the results depend on the processing

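The central nervous system covariate and the fit without the 2 libraries low in those transcripts were chosen after the data were seen, and the cause of each move below was not tested. The limits were 2 or 3 libraries per group, a tissue mixture that differs between libraries, no statement that libraries came from separate animals, and list tests that rest on a preset correlation. Over all 28 lists in 7 comparisons, 0 were called with an estimated correlation and 0 with fry. Neither was tested on a list known to have moved, so these counts do not show that no list moved.

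With the DESeq2 Wald test the genes changed were 1 for OVX-PBS against sham, 32 for OVX-ZA against OVX-PBS, 29 for OVX-HA against OVX-ZA, 14 for OVX-PPA against OVX-ZA and 15 for OVX-ZA against sham. With no low-count filter they were 3 for OVX-ZA against OVX-PBS, 8 for OVX-HA against OVX-ZA and 2 for OVX-ZA against sham. With only the 2 groups they were 1 for OVX-ZA against OVX-PBS and 0 for OVX-HA against OVX-ZA, and on the deposited table with limma 2 and 3. With the muscle covariate 0 were left for OVX-HA against OVX-ZA. With the nervous system covariate they were 6 for OVX-ZA against OVX-PBS, 9 for OVX-HA against OVX-ZA, 5 for OVX-PPA against OVX-ZA and 5 for OVX-ZA against sham, and without the 2 low libraries 6, 4, 2 and 2. Leaving out 1 library gave 0 to 1 for OVX-ZA against OVX-PBS (1 without OVX-ZA replicate 2) and 0 to 4 for OVX-HA against OVX-ZA (4 without OVX-HA replicate 2). Counts of genes with unadjusted p below 0.05 also moved with single libraries. For OVX-PPA against OVX-PBS the count of 408 was 890 without OVX-PBS replicate 3 and 229 without OVX-PBS replicate 1, and for OVX-ZA against OVX-PBS 731 was 413 without OVX-PBS replicate 1. For OVX-HA against OVX-PPA 260 was 1084 without OVX-HA replicate 2, 430 without OVX-HA replicate 1 and 406 without OVX-PPA replicate 2, and for OVX-HA against OVX-ZA 820 was 1336 and 1850 without OVX-HA replicates 1 and 3 and 462 without OVX-ZA replicate 1. Against sham, 378 for OVX-HA was 721, 780 and 583 without OVX-HA replicates 1 to 3, and 607 for OVX-ZA was 923 without sham replicate 3 and 382 without OVX-ZA replicate 1. With replicate number as a block 0 genes were left for OVX-HA against OVX-ZA, and 3 lists were called between OVX-HA and OVX-PPA at the preset correlation. The block rests on a number alone. Deviations from the group mean correlated at a median of 0.018 between samples with the same replicate number and 0.0125 between other pairs from different groups.

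At the preset correlation, leaving out 1 library gave 10 to 20 lists for OVX-PBS against sham (10 without OVX-PBS replicate 1), 8 to 15 for OVX-HA and 10 to 14 for OVX-PPA against OVX-PBS, 11 to 19 for OVX-ZA against OVX-PBS, 4 to 12 for OVX-HA against OVX-PPA, 14 to 18 for OVX-HA and 9 to 18 for OVX-PPA against OVX-ZA. The muscle covariate gave 16 lists for OVX-HA and 13 for OVX-PPA against OVX-PBS. Without the 2 low libraries there were 15 for OVX-PPA against OVX-PBS and 12 for OVX-HA against OVX-PPA, and with the nervous system covariate 10 for OVX-HA against OVX-PPA.

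Some list differences from other genes turned direction, and ranges below are over leaving out 1 library. In OVX-PBS against sham these were erythroid (-0.103), cell cycle (-0.0766) and ribosomal (-0.0179) with the nervous system covariate, mitochondrial without the 2 low libraries (-0.0271) or without OVX-PBS replicate 1 (-0.0263; range -0.0263 to 0.45), and T and NK cell without sham replicate 3 (0.139; range -0.63 to 0.139). Against OVX-PBS they were collagen in OVX-HA without OVX-PBS replicate 1 (0.00127, range -0.30 to 0.00127) and ribosomal in OVX-PPA with the nervous system covariate (0.00746). In OVX-HA against OVX-PPA they were monocyte without OVX-PPA replicate 2 (0.242, range -0.55 to 0.242) and ribosomal with the covariate (-7.2e-04), without the 2 low libraries (-0.0913) and without OVX-HA replicate 2 (-0.0914, range -0.0914 to 0.33). In OVX-HA against OVX-ZA, without the 2 low libraries and without OVX-HA replicate 2, they were erythroid (-0.127 and -0.128, range to 0.75), cell cycle (-0.139 and -0.140, range to 0.70), collagen (-0.0746 and -0.0755, range to 0.24) and ribosomal (-0.0898 and -0.0908, range to 0.33), with collagen also at -0.0137 with the covariate and -0.0423 without OVX-ZA replicate 2. In OVX-PPA against OVX-ZA they were B cell without OVX-PPA replicate 2 (-0.0558, range to 0.99), and monocyte (0.101, range from -0.70) and immunoglobulin (0.400, range from -1.57) without OVX-PPA replicate 1.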

Other observations

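Chosen only after the result was seen were the marker lists of other tissues, the covariate built on nervous system transcripts and the hypotheses below. Brown fat transcripts were present in every library, with Ucp1, the uncoupling protein of brown fat, at 12.3 to 224 CPM and Cidea, a lipid droplet protein, at 10.8 to 115. The Schwann cell gene Pmp22 (153 to 269 CPM) and the sensory neuron gene Avil (29.2 to 78.2) were read in all 14 libraries, also in the 2 libraries with little Mobp. Cxcl13, a chemokine of lymph node follicles, read 6.61 CPM in sham replicate 3, 2.46 in OVX-ZA replicate 1 and 7.92 in OVX-ZA replicate 2. Hindlimb genes were low, with Pitx1 at a median of 0.257 CPM, Hoxa11 at 1.77 and Hoxc11 at 2.31, beside trunk genes such as Hoxa5 at 13.2 and Hoxb9 at 18.1. Part of these followed the nervous tissue, since OVX-HA replicate 2 and OVX-PBS replicate 1 read 0.29 and 0 CPM for Hoxa11, 0.53 and 0.21 for Hoxc11, and 5.92 and 5.08 for Hoxb9 (10.7 to 29.5 in the other 12 libraries). Hoxd11 read 0 in both. Other trunk genes kept most of their level there, with Hoxa5 at 10.8 and 14.3, Hoxc6 at 18.6 and 22.9 and Hoxa7 at 19.3 and 19.1. The hindlimb genes Tbx4 (1.14 and 1.37) and Pitx1 (0.41 and 0.74) were not lower there.

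One hypothesis is that osteoclasts or their fusing precursors were more numerous, or carried more fusion transcripts, under zoledronic acid. Ocstamp and Dcstamp differed more than Acp5 did (2.40 and 2.17 against 0.66). Counting TRAP-stained osteoclasts and their nuclei on tibia sections of OVX-ZA and OVX-PBS mice, with in situ hybridization for Ocstamp, would separate cell number from transcripts per cell. Another hypothesis is that bone-forming cells made less osteocalcin and type I collagen transcript while Alpl stayed near OVX-PBS (-0.04), as in reduced remodeling. Serum osteocalcin and P1NP with dynamic labels in the same mice would test it. The nervous tissue transcripts may come from spinal cord and sensory ganglia, with the sensory ganglion gene Pou4f1 at 6.68 to 18.3 CPM over all libraries. Whether such tissue was mixed into tibia samples or came with vertebral column in place of tibia was not told by the values (Tbx4 median 1.02 CPM). Resequencing tibia cleaned of soft tissue, with Mobp and Scn10a measured by PCR before library preparation, would test the source. The lower adipocyte genes in OVX-HA could reflect less marrow fat or less brown fat adhering to the sample, since Ucp1 was 24.1 and 12.3 CPM in OVX-HA replicates 2 and 3, the OVX-HA libraries with the lowest adipocyte means, against 139 in replicate 1. Adipocyte means tended to follow Ucp1 in other groups as well. Sham replicates 1 to 3 read 224, 63.5 and 218 CPM of Ucp1 beside adipocyte means of 6.25, 5.41 and 6.48 log2 CPM. OVX-ZA replicates 1 to 3 read 118, 92.0 and 56.5 CPM beside 6.13, 6.07 and 5.63. These values go with brown fat that differed between samples, but they do not exclude less marrow fat. The interval of the list mean in OVX-HA (-1.19 to 0.42) included 0, and neither source was tested. Osmium staining of marrow fat in the tibia, with Ucp1 measured in cleaned bone, would separate them.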
